A study of Arabidopsis thaliana with 6 samples.

How the data were processed

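The series holds 6 poly(A) RNA libraries of hand-dissected Arabidopsis thaliana embryos, 1 for each of 3 stages and 2 directions of the cross between Col-0 and Cvi-0. Per the labels' protocols, flowers were emasculated before crossing, embryos were washed extensively, RNA of pools of 20 embryos was amplified linearly, and libraries kept the strand. Per the series' design text, reads were mapped with Bowtie to the Col-0 genome and transcript models of TAIR10 and to a version of both in which known variants were replaced by those of Cvi-0. Only perfect and unique matches were kept. The version of Bowtie and the counting program are not given in the sources used here. Per the file headers, the deposited values are read counts per gene that overlap variant positions, for each allele, and the reads of each gene. The deposited reads per gene come in steps of 0.5 and were treated as estimated counts. A step of this kind arises where a read matching only 1 of the genomes adds 0.5. That reading was inferred from the values: doubled gene reads and allele reads had the same parity in 93.1% of 119232 entries. The authors also deposited gene reads as RPM, scaled to each library's total of mapped reads, and these are the RPM printed. Lists of reads per variant, deposited beside them, were used for 1 alternative and for the number of variants per gene. A list can count a read at several variants, and it summed above the gene's tally in 2841 entries (2.38%). In 6 entries the deposited total of variant reads differed from the sum of the alleles. Another 12 columns of values, other forms of the same libraries, were not used here.

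Perfect matching to an edited genome loses reads that carry a variant not in the list, more often from Cvi-0 than from Col-0, and can give a gene wholly to 1 allele where the listed variant is wrong. Unique matching removes reads shared by near-identical genes. Linear amplification of small amounts of RNA adds noise beyond counting. Genes were matched to the TAIR10.1 annotation by locus identifier (23747 of 23874 genes), which gave symbols, products and coordinates. The mother was taken as the parent named first. A check of that order with genes encoded in organelles was void, because 0 such identifiers were among those analysed here.

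Allele counts were tested in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with glmQLFit and glmQLFTest on the 12 allele columns, for genes with a mean of at least 10 allele reads per library. The terms were library, allele genotype and parent. Both columns of a library had the same offset, its total of allele reads, so that a general excess of 1 parent was kept. For each stage, parent was fitted within stage with 1 genotype effect for all stages, and the change between stages was tested in that fit. Gene reads were rounded to whole numbers, filtered with filterByExpr, scaled with TMM (factors 0.855 to 1.11) and fitted with stage and cross as terms. Residual degrees of freedom were 4 for the parent effect over all stages and 2 for the other fits, and the biological coefficient of variation was 30.8% for the parent effect over all stages, 32.0% per stage and 42.9% for expression. Since no group had a replicate, stages served as repeats for the parent and cross effects, and the reciprocal crosses as repeats for the stage effects. A p-value measures the spread left in these fits, not that between repeated samples of a group. The standard error is the log2 ratio divided by the square root of F. Adjustment was by Benjamini-Hochberg with a threshold of 0.05.

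Shares of reads have exact Clopper-Pearson 95% intervals. Where 1 side had 0 reads the fold is a lower bound against a floor of 3 reads over the group, scaled by library size for whole genes. The exact binomial count per stage took genes with at least 5 allele reads in both libraries. Gene lists, with camera at a preset correlation of 0.01, at an estimated correlation, and fry, covered imprinted genes of the endosperm (maternal and paternal), seed coat, endosperm, pollen and sperm, egg and female gametophyte, embryo patterning, embryo maturation, cell cycle, chromatin silencing, photosynthesis and ribosomal proteins. Lists with fewer than 3 measured genes were not tested. The estimated correlation was not always above the preset. For the parent effect it was -0.073 for seed coat genes. From the 1-cell/2-cell to the 8-cell stage it was 0.005 for cell cycle genes and 0.342 for ribosomal protein genes. A higher p with an estimated correlation is therefore not in itself a sign that genes of a list vary together. Many listed genes are also expressed in embryos, so a list marks a tissue only loosely.

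Designs, filters, lists and the rule for naming genes were set before the data were examined. The rule took the 10 genes with the largest log2 change in each direction past the threshold (5 for genotype and cross), on the same parent's side in every library with at least 5 allele reads for the parent effect, and without overlap between the libraries of the stages for expression. It also took up to 4 members of each list with the smallest p and, where fewer than 5 genes passed, the 5 with the smallest p in each direction. Genes named outside it (AT5G47350, MBP2 and AT2G24693 over all stages, PDIL1-5, RBCS2B, LEC1 and KNOLLE in some comparisons, and stage shares of PDF1 and PIP3) were chosen after their values were seen. Reading the same-side rule within a stage, the comparison of the 32-cell with the 1-cell/2-cell stage, list tests between the crosses, and list medians under other scalings were also added after the data were seen.

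The steps were checked on simulated counts with the real means and library sizes and 200 changed genes. For the parent effect over all stages the share of changed genes called was 36.0%, 80.0%, 100% and 98.0% at 2-, 4-, 8- and 16-fold, with 9 false calls among 6785 unchanged genes. For the parent effect at the 8-cell stage it was 12.0%, 22.0%, 58.0% and 82.0%, and for the change between stages 4.00%, 18.0%, 42.0% and 60.0%. From the 1-cell/2-cell to the 8-cell stage it was 8.00%, 52.0%, 66.0% and 78.0%, and from the 8-cell to the 32-cell stage 0%, 32.0%, 54.0% and 72.0%. False calls made up 5.42%, 13.9%, 26.2%, 9.73% and 12.2% of all calls in these 5 simulations, in the order given, so that the tests with 2 residual degrees of freedom exceeded their nominal rate. The binomial count recovered 80.3% to 83.3% of changed genes with 0 false calls. This recovery was not split by fold. It cannot be set beside the shares by fold above, and gives no recovery for a change of a given size. The simulated reads of the binomial count had counting error alone, with no further spread and no genotype effect. They therefore give no false call rate for the real reads. Camera called a list of 30 doubled genes in both stage comparisons, and 0 and 3 of 100 unchanged lists. The simulated genes were drawn independently, so this gives no false call rate for lists whose genes vary together.

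Alternatives were other filters (no filter, a mean of at least 50 allele reads, at least 20 reads), TMM on allele columns, DESeq2 1.42.0, a pooled binomial test, removal of genes with under 5% of reads from 1 genotype, the variant with the most reads alone, a genotype effect per stage, library totals, no cross block, single alleles, other folds and thresholds, and each library left out. Adding 0.5 of the allele reads to gene reads was an alternative chosen after seeing the data. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and minimap2 2.31 to align the mitochondrial genome to chromosome 2 (blocks of at least 10000 bases).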

Results

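Poly(A) RNA was measured in hybrid embryos of Arabidopsis thaliana made by crossing the inbred accessions Col-0 and Cvi-0 in both directions. Each library came from a pool of 20 hand-dissected embryos, taken about 40 h (1-cell/2-cell stage), 64 h (8-cell stage) or 78 h (about 32-cell stage) after pollination. The 3 stages and 2 cross directions gave 6 groups with 1 library each, so no group had a replicate. In a cross the mother is named first, by the usual convention, so that Col-0 x Cvi-0 embryos had a Col-0 mother. Reads falling on single-nucleotide differences between the accessions were assigned to the Col-0 or the Cvi-0 allele, and thereby to the mother or the father. The libraries held between 10299142 (8-cell, Col-0 x Cvi-0) and 14805499 (32-cell, Cvi-0 x Col-0) reads over genes. Allele reads numbered 1269419 and 1291813 at the 1-cell/2-cell stage, 1233554 and 1478543 at the 8-cell stage, and 1635773 and 1723728 at the 32-cell stage, with Col-0 x Cvi-0 given first. Reads fell on 23874 genes in at least 1 library and on 16393 genes in all 6, and 15828 genes had allele reads.

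The first question was how much of the embryo transcriptome came from each parental genome. With a Col-0 mother, the maternal share of allele reads was 53.7% (95% Clopper-Pearson interval 53.6 to 53.8) at the 1-cell/2-cell stage, 54.0% (53.9 to 54.1) at the 8-cell stage and 53.5% (53.4 to 53.5) at the 32-cell stage. With a Cvi-0 mother it was 46.2% (46.1 to 46.3), 46.8% (46.7 to 46.9) and 47.1% (47.0 to 47.1) at the same stages. The side above 50% therefore followed the Col-0 allele, not the mother, in each of the 6 libraries. Averaged over the reciprocal crosses on the log2 ratio scale, which removes a difference between the genotypes, the maternal share was 49.95% (49.89 to 50.01), 50.41% (50.35 to 50.47) and 50.27% (50.22 to 50.33) from the earliest stage to the latest. Intervals and floors here and below cover counting error only, since reads of amplified RNA are not independent molecules. With 1 library per group these shares have no replicate check.

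**Figure D1:**
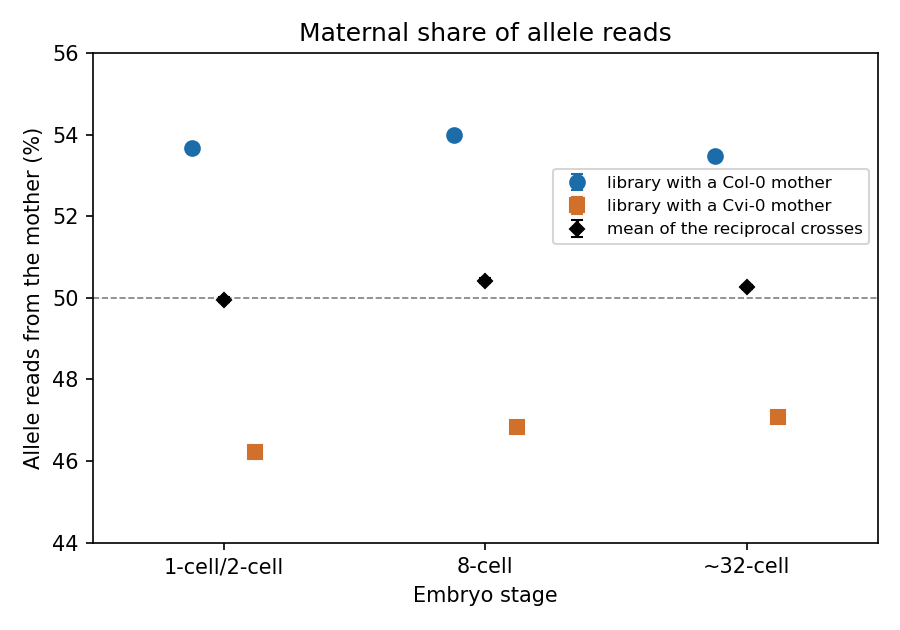
Maternal share of allele reads in percent (vertical axis) against embryo stage (horizontal axis) for each library, by mother, with black diamonds for the mean of the reciprocal crosses; 95% intervals are smaller than the symbols. Libraries with a Col-0 mother sit between 53.5% and 54.0%, those with a Cvi-0 mother between 46.2% and 47.1%, and the means between 49.95% and 50.41%.

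Single genes were then tested for unequal reads from mother and father over all stages. Among 6985 genes, 9 had more maternal than paternal reads and 0 had more paternal reads. TT4, chalcone synthase (AT5G13930, chromosome 5, 4488476 to 4490264, TAIR10.1), had 426 maternal and 3 paternal reads, a maternal share of 99.3% (98.0 to 99.9) and a log2 ratio of 7.22 ± 0.55 (SE; adjusted p = 0.000365). TT18, leucoanthocyanidin dioxygenase (AT4G22880, chromosome 4, 12004726 to 12006209), had 147 maternal and 0 paternal reads, at least 49.0-fold more from the mother against a floor of 3 reads over the 6 libraries (adjusted p = 0.011). BAN, anthocyanidin reductase of the proanthocyanidin pathway (AT1G61720), had 177 maternal reads and 1 paternal read, a share of 99.4% (96.9 to 100) and a log2 ratio of 6.61 ± 0.76 (adjusted p = 0.00358).

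Other genes of this set were the proline-rich protein gene PRP4 (AT4G38770; 291 and 2 reads, 99.3%, interval 97.6 to 99.9; log2 7.05 ± 0.70), GILT (AT4G12960; 589 and 11 reads, log2 6.32 ± 0.62) and the lipid transfer protein gene LTP6 (AT3G08770; 280 and 4 reads, log2 5.85 ± 0.56). These genes and TT4, TT18 and BAN had a maternal majority in every library with at least 5 allele reads. AT5G47350 (2184 and 69 reads, log2 5.34 ± 0.63) and MBP2 (AT1G52030; 473 and 47 reads, log2 4.96 ± 0.76) passed the test, but in the 1-cell/2-cell Col-0 x Cvi-0 library their maternal shares were 45.1% and 46.5%. The 32-cell Cvi-0 x Col-0 library held 1691 of the maternal reads of AT5G47350. AT2G24693 (771 and 354 reads, log2 1.45 ± 0.21) also passed, with a maternal share of 36.9% (32.7 to 41.4) over the Col-0 x Cvi-0 libraries. On the paternal side no gene passed. AT3G47040 came nearest, with a log2 ratio of -1.25 ± 0.25 from 146 maternal and 328 paternal reads (adjusted p = 0.114). RGTA2 (-3.39), AT2G20100 (-3.30, adjusted p = 0.386), AT1G48700 (-1.48) and VPS60;2 (-0.84) were also short of the threshold.

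The test was edgeR's quasi-likelihood F test with library, allele genotype and parent as terms and Benjamini-Hochberg adjustment, as for all adjusted p-values of single genes below. At an unadjusted threshold of 0.05 it passed 301 genes. DESeq2 called 20 genes higher from the mother and 2 from the father. The 95% interval of the log2 ratio lay within a 2-fold difference for 3251 genes (46.5%) and within a 4-fold difference for 6068 genes (86.9%). Without the 32-cell Cvi-0 x Col-0 library 4 genes were called, and TT18 (adjusted p = 0.0955, bound 27.7-fold) and BAN (adjusted p = 0.052) were not among them.

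**Figure D2:**
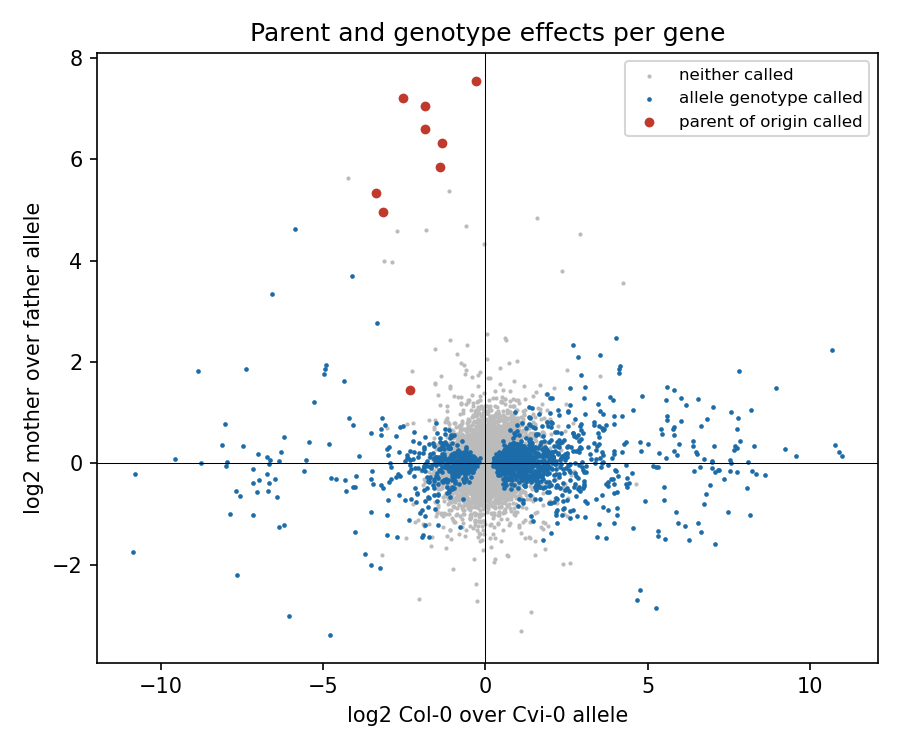
Each point is 1 of the 6985 genes, placed by its fitted log2 ratio of Col-0 over Cvi-0 allele (horizontal) and of mother over father allele (vertical), and coloured by the test it passed; fitted ratios of genes with 0 reads of 1 allele are not bounds. The 9 genes with a maternal excess are coloured for it whether or not they are among the 1430 genes whose alleles differed by genotype. Of the 9, AT2G24693 has the lowest ratio of mother over father.

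**Figure D3:**
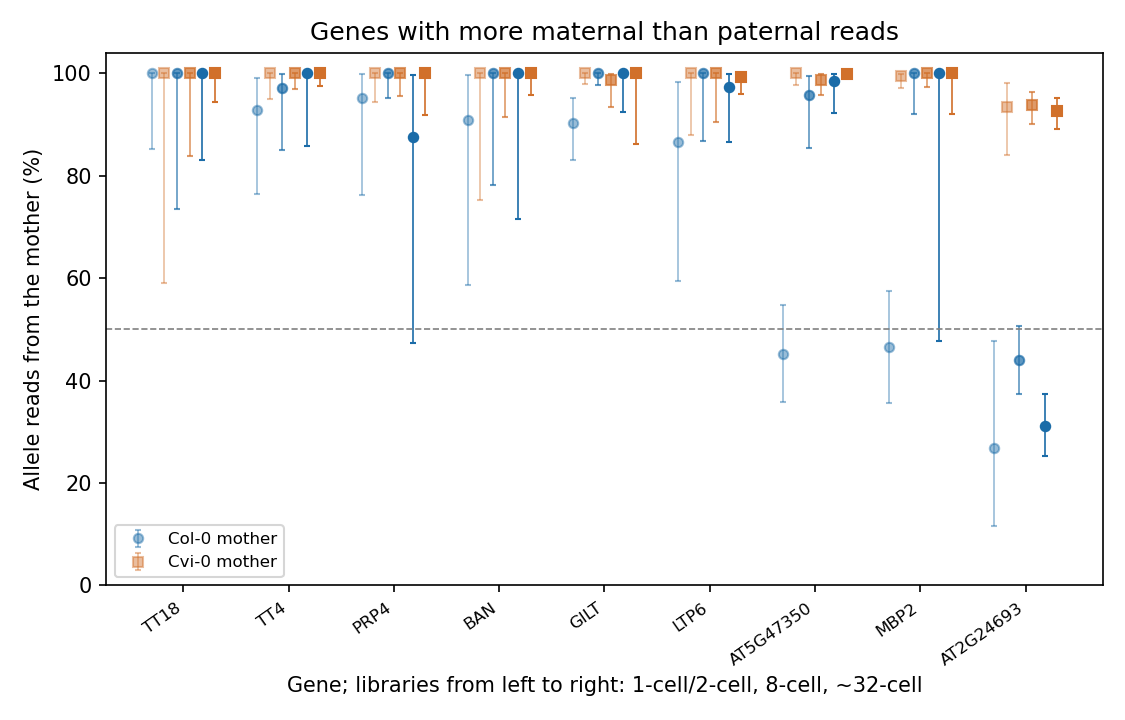
Maternal share of allele reads in percent with its 95% Clopper-Pearson interval, per library, for the 9 genes with more maternal reads; colours give the mother, and darker points are later stages. AT5G47350 and MBP2 fall to 45.1% and 46.5% in the 1-cell/2-cell Col-0 x Cvi-0 library, and AT2G24693 lies below 50% with a Col-0 mother at each stage.

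Of 7 seed coat genes measured, 3 were higher from the mother over all genes tested (TT4, TT18 and BAN) and 5 when adjusted over the list alone, and the median log2 ratio was 5.37, also with TT18 at its bound. TT3, dihydroflavonol reductase, had 62 maternal reads and 1 paternal read (98.4%, interval 91.5 to 100; log2 5.37 ± 1.02, adjusted p = 0.115 over all genes), and TT6, flavanone 3-hydroxylase, had a log2 ratio of 1.72. GL2 (-0.30 ± 0.56) and STK (-0.01 ± 0.62), transcription factor genes of the same list, were near 0. The list stood apart from other genes by camera (adjusted p = 1.47e-10, and adjusted p = 0.0161 with an estimated correlation). Of 7 photosynthesis genes 0 were called over all genes and 1 when adjusted over the list alone, RBCS2B, a Rubisco small subunit gene of a multigene family (145 and 4 reads, log2 4.60 ± 0.79). That list passed camera with the preset correlation (adjusted p = 0.00123) but had adjusted p = 0.326 with an estimated correlation.

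No other list was called by camera for the parents. The adjusted p was 0.794 for 19 embryo patterning genes, 0.829 for 4 maturation genes, 0.626 for 16 cell cycle genes, 0.109 for 16 chromatin silencing genes and 0.761 for 206 ribosomal protein genes, and 0 members of these were called over all genes or adjusted over the list alone. LEC1, a regulator of embryo identity, had 3779 maternal and 3733 paternal reads (50.3%, interval 49.2 to 51.4), and KNOLLE, the cytokinesis syntaxin, had 2889 and 2877 (50.1%, interval 48.8 to 51.4). Lists with fewer than 3 measured genes were not tested as lists. Their members were SAC2 among paternally expressed imprinted genes (log2 0.24), SUC5 (0.29) and ALE1 (0.24) among endosperm genes, VGD1 (0.78) among pollen genes and EC1;5 (0.53) among egg cell genes, with 0 called, and 0 maternally expressed imprinted genes were measured.

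At the 1-cell/2-cell stage, 6 genes had more maternal and 4 more paternal reads. PRP4 (log2 6.54 ± 1.05), TT4 (6.10 ± 0.91) and GILT (5.29 ± 0.79) were again higher from the mother, as were AT2G32690, a glycine-rich protein gene (2.55 ± 0.44; 88 and 15 reads), and ABCG15, an ABC transporter gene (2.11 ± 0.35; 154 and 43 reads), each with adjusted p = 0.0396. PDIL1-5 also passed (4.42 ± 0.81), though its maternal excess was not present in both crosses. The paternal side held PIP3, an aquaporin (-1.24 ± 0.18; 912 maternal and 2118 paternal reads), PDF1, an epidermal marker gene (-1.31 ± 0.23; 164 and 415 reads), AT1G71691, a GDSL lipase gene (1 and 38 reads, a maternal share of 2.56%, interval 0.0649 to 13.5), and the glucosyltransferase gene UGT73B4 (0 and 46 reads, at least 15.3-fold lower from the mother; 5.67-fold without the Cvi-0 x Col-0 library of that stage; a member of a multigene family, so its reads are uncertain). DI21 was short of the threshold (-0.95, adjusted p = 0.0835). An unadjusted threshold of 0.05 passed 406 genes, and DESeq2 called 7. The count was sensitive to every library: without each one in turn it was 9 maternal and 7 paternal (1-cell/2-cell Col-0 x Cvi-0), 2 and 3 (1-cell/2-cell Cvi-0 x Col-0), 1 and 0 (either 8-cell library), 13 and 14 (32-cell Col-0 x Cvi-0) and 10 and 11 (32-cell Cvi-0 x Col-0).

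At the 8-cell stage 7 genes were higher from the mother and 0 from the father. VSP1, a vegetative storage protein gene, had 195 maternal and 0 paternal reads (at least 65.0-fold), MBP2 187 and 0 (at least 62.3-fold), PRP4 156 and 0 (at least 52.0-fold) and LTP6 63 and 0 (at least 21.0-fold). Without the 8-cell Cvi-0 x Col-0 library these bounds were 24.7, 15, 25 and 8.67. GILT (log2 8.40 ± 1.1; 239 and 1 reads, 99.6%, interval 97.7 to 100), TT4 (7.34 ± 0.95; 151 and 1 reads, 99.3%, interval 96.4 to 100) and AT5G47350 (5.99 ± 0.77; 209 and 4 reads) completed the set. AT1G43245, AT5G45560, AT4G02860, RGTA2 and AT5G05060 were the nearest on the paternal side, all short of the threshold. The test passed 279 genes at an unadjusted 0.05, and DESeq2 called 3. Leaving out 1 library gave 0 genes (8-cell Col-0 x Cvi-0), 4 maternal and 0 paternal (8-cell Cvi-0 x Col-0), 15 and 0 (1-cell/2-cell Col-0 x Cvi-0), 14 and 0 (1-cell/2-cell Cvi-0 x Col-0), 24 and 4 (32-cell Col-0 x Cvi-0) or 20 and 3 (32-cell Cvi-0 x Col-0).

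At the 32-cell stage 3 genes were higher from the mother and 0 from the father. AT5G47350 had 1759 maternal and 3 paternal reads (99.8%, interval 99.5 to 100; log2 7.70 ± 0.70, adjusted p = 0.000146), TT4 178 and 0 (at least 59.3-fold, and 8.00-fold without the 32-cell Cvi-0 x Col-0 library) and LTP6 175 and 2 (98.9%, interval 96.0 to 99.9; log2 6.01 ± 0.89, adjusted p = 0.0274). Of the maternal reads of AT5G47350, 1691 came from the Cvi-0 x Col-0 and 68 from the Col-0 x Cvi-0 library. GILT (adjusted p = 0.0526) and MBP2 (adjusted p = 0.161) were short of the threshold, as were CYP78A5 (-0.79), AT1G21940, AT1G65370, AT1G23390 and AT5G10950 on the paternal side. The test passed 92 genes at an unadjusted 0.05, and DESeq2 called 4. Without 1 library the count was 8 maternal and 1 paternal (1-cell/2-cell Col-0 x Cvi-0), 6 and 0 (1-cell/2-cell Cvi-0 x Col-0), 5 and 1 (32-cell Col-0 x Cvi-0) or 8 and 7 (32-cell Cvi-0 x Col-0).

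Whether the parental ratio itself changed between stages was tested in the same model, and 0 genes passed in edgeR (186 at an unadjusted 0.05). DESeq2's likelihood ratio test also called 0 (75 at an unadjusted 0.05). The smallest p-values belonged to ABCG15, with maternal shares of 78.2%, 38.8% and 48.6% over the stages (adjusted p = 0.314), VSP1 and UGT73B4 (both adjusted p = 0.448) and MBP2 (adjusted p = 0.66). PDF1 had maternal shares of 28.3% (24.7 to 32.2), 43.1% (42.1 to 44.1) and 51.1% (50.5 to 51.8), and PIP3 30.1%, 44.7% and 50.3%. Without the 32-cell libraries the test called 10 (Col-0 x Cvi-0) and 21 genes (Cvi-0 x Col-0), and without either 1-cell/2-cell library 1. Seed coat genes were above other genes at each stage by camera (adjusted p = 1.06e-07, 5.04e-05 and 3.08e-07), with adjusted p = 0.378, 0.308 and 0.8 with an estimated correlation. Photosynthesis genes were called too at the 1-cell/2-cell (adjusted p = 0.00511) and 8-cell stages (adjusted p = 0.000225) but not at the 32-cell stage (adjusted p = 0.854), with 0 of 7 called over all genes at each stage and adjusted p = 0.557, 0.308 and 0.927 with an estimated correlation. No other list was called at a single stage. No list changed its parental ratio between stages, the smallest adjusted p being 0.0616 for photosynthesis genes between the 8-cell and 32-cell stages.

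A separate count used the reads of both reciprocal libraries of a stage, asking for a ratio of at least 4-fold on the same parent's side in each by an exact binomial test. It describes these libraries, not the conditions. At the 1-cell/2-cell stage 32 genes were maternal and 20 paternal among 7144, at the 8-cell stage 31 and 7 among 6893, and at the 32-cell stage 11 and 1 among 7778. Maternal genes in at least 1 stage numbered 60, of which 9 were maternal in at least 2 stages and 5 in all 3, whereas of 27 paternal genes 1 was paternal in 2 stages and 0 in all 3.

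The accession of the allele made a larger difference than its parent. Of 6985 genes, 954 were higher from the Col-0 and 476 from the Cvi-0 allele (66.7% on the Col-0 side), and with TMM scaling of the allele columns the split was 794 and 652 (54.9%). ACS2, an ethylene biosynthesis enzyme, had 4677 Col-0 and 5 Cvi-0 reads (log2 10.68 ± 0.36, adjusted p = 1.01e-08). AT5G43065 (1527 Col-0 reads, at least 509-fold), AT1G35320 (1442, at least 481-fold), AT3G03130 (1333, at least 444-fold) and AT4G09930 (572, at least 191-fold) had 0 Cvi-0 reads. On the other side, AT2G15555 had 3 Col-0 and 4180 Cvi-0 reads (a Col-0 share of 0.0717%, interval 0.0148 to 0.209), and OFP9, a transcriptional repressor gene, 5 and 1348 (log2 -8.84 ± 0.56). SAP130a (1329 Cvi-0 reads, at least 443-fold, and uncertain because of a near-identical copy), AT3G43833 (573, at least 191-fold) and AT5G03880 (326, at least 109-fold) had 0 Col-0 reads. The count was between 1007 and 1293 when each library was left out. A sequence that differs from the assumed Cvi-0 variant gives the same reading as an allele with no expression.

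Expression of whole genes was compared between stages on the deposited reads per gene, without regard to allele, and with the cross direction as a block. Between the 1-cell/2-cell and 8-cell stages 151 genes rose and 41 fell among 17478. TMO6, a transcription factor gene downstream of auxin signalling (AT5G60200), had 0 reads at the 1-cell/2-cell stage and 10.3 ± 3.26 RPM (SD, n = 2, 1 library of each cross) at the 8-cell stage, at least 88.6-fold higher. With 0 reads at the earlier stage there were also AT2G14846, a lipid-transfer protein-like gene (at least 95.5-fold), SOB3 (at least 88.3-fold), AT5G57130 (at least 64.0-fold), AT2G20463 (at least 59.5-fold), GSTU25 (at least 47.6-fold), the gibberellin-inactivating oxidase gene GA2OX2 (at least 34.95-fold), FOP1 (at least 30.9-fold) and AT2G02490 (at least 27.0-fold). With 1 library left out the lowest bounds were 41.1 for AT2G14846 and SOB3 (8-cell Cvi-0 x Col-0) and, without the 1-cell/2-cell Cvi-0 x Col-0 library, 43.6 for TMO6, 31.5 for AT5G57130, 29.2 for AT2G20463, 23.4 for GSTU25, 17.2 for GA2OX2, 15.2 for FOP1 and 13.3 for AT2G02490. GH9B9, a glycosyl hydrolase gene, went from 2 reads to 768, a ratio of 359 with a 95% counting interval of 99.2 to 2974, or at least 118-fold without the 1-cell/2-cell Cvi-0 x Col-0 library, which held both reads.

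Among genes that fell, MIOX4 and MIOX2 encode myo-inositol oxygenases. MIOX4 went from 60.9 ± 42.6 to 1.00 ± 0.51 RPM (log2 -5.65 ± 0.48, adjusted p = 0.006) and MIOX2 from 19.3 ± 8.46 to 0.337 ± 0.0478 RPM (log2 -5.76 ± 0.72). AT4G27450 (-6.43 ± 0.87), AT2G25450 (-6.01), AT4G35770 (-5.87 ± 0.70), the pectin acetylesterase gene AT5G45280 (-5.08 ± 0.56), the annexin gene ANN6 (-5.06), BT1 (-4.81), AT2G20670 (-4.63 ± 0.40) and AT2G39400 (-4.61) also fell. The test passed 2267 genes at an unadjusted 0.05, and DESeq2 called 500 higher and 314 lower. Without 1 library the count was 72 (8-cell Col-0 x Cvi-0), 49 (8-cell Cvi-0 x Col-0), 410 (32-cell Col-0 x Cvi-0) or 493 (32-cell Cvi-0 x Col-0). Scaling by library totals in place of TMM moved the median log2 change of all genes from 0.01 to -0.18.

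Of 40 embryo patterning genes measured, 6 were higher at the 8-cell stage over all genes tested and 16 when adjusted over the list alone, with 0 lower, and the median log2 change was 0.40 with 25 of 40 above 0. PDF1 went from 88.6 ± 12.5 to 1207 ± 2.54 RPM (log2 3.94 ± 0.30, adjusted p = 0.00542), and TMO6, the root patterning regulator SHR (2 reads, then 177, a ratio of 82.8 with a counting interval of 22.6 to 690, or at least 27.2-fold without the 1-cell/2-cell Cvi-0 x Col-0 library; adjusted p = 0.025), the leaf polarity gene REV (log2 2.54 ± 0.39), the homeodomain gene AT4G04890 (1.93 ± 0.32) and the root stem cell regulator PLT1 (1.71 ± 0.30) were the others. Camera gave adjusted p = 1.01e-05 for the list, and adjusted p = 0.245 with an estimated correlation. Of 39 cell cycle genes 1, CYCA2;3, rose (log2 2.39 ± 0.35, adjusted p = 0.0251), with 10 when adjusted over the list alone. Camera gave adjusted p = 0.00307, and adjusted p = 0.245 with an estimated correlation, which was 0.005 and so below the preset. The camera call of the cell cycle list was lost without the 8-cell Col-0 x Cvi-0 library (adjusted p = 0.0507). CDC20;1, an activator of the anaphase-promoting complex, had a log2 change of 1.97 ± 0.38 (adjusted p = 0.0703).

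**Figure D4:**
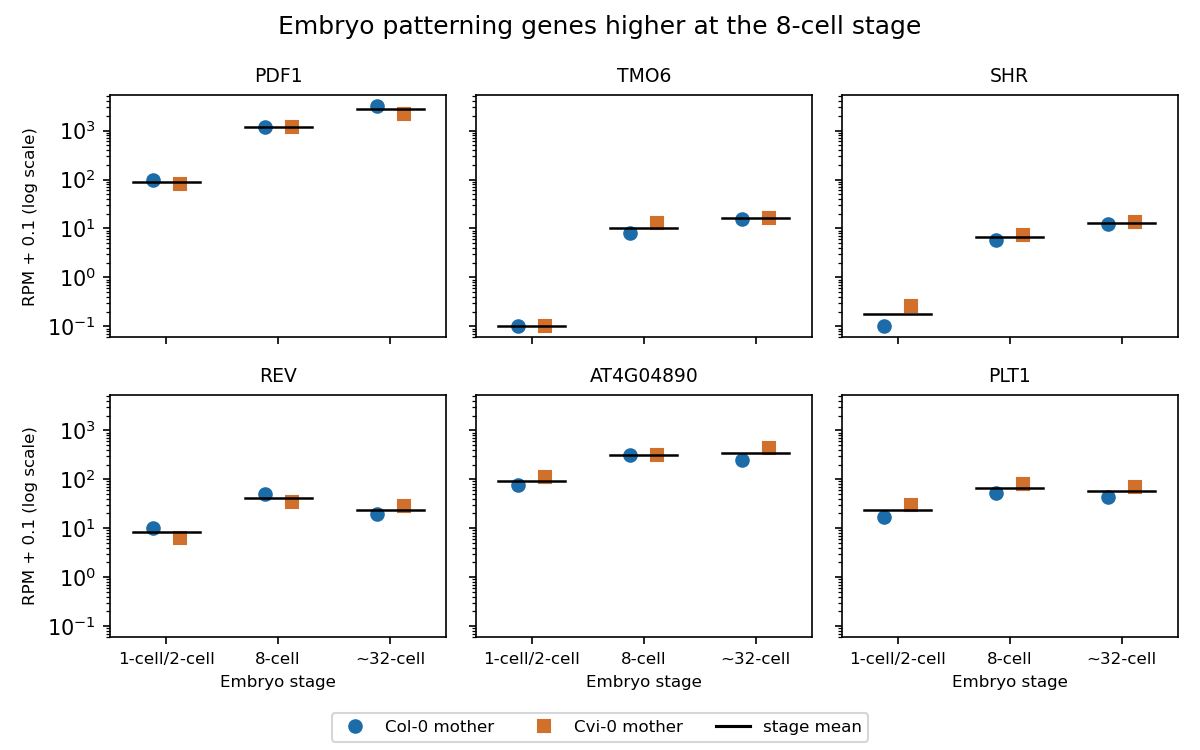
Normalised reads (RPM as deposited, with 0.1 added, logarithmic vertical axis) at each stage for the 6 embryo patterning genes that rose at the 8-cell stage; points are single libraries by mother and bars are stage means. TMO6 has 0 RPM in both 1-cell/2-cell libraries, and PDF1 goes from 88.6 through 1207 to 2703 RPM.

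Of 4 imprinted genes known as paternally expressed in endosperm, 0 passed over all genes and 3 were lower when adjusted over the list alone: PEG2 (78.5-fold, counting interval 21.4 to 654, with 2 reads at the 8-cell stage), PEG9 (65.2-fold, 17.7 to 544, also 2 reads) and SAC2 (log2 -1.16 ± 0.35). The fall of PEG2 rested mostly on the 1-cell/2-cell Col-0 x Cvi-0 library (10.6 RPM, against 1.01 RPM with a Cvi-0 mother), without which it was 13.7-fold (3.09 to 125). Camera gave adjusted p = 0.00199 for this list and adjusted p = 0.245 with an estimated correlation, and without the 1-cell/2-cell Cvi-0 x Col-0 library the preset value was 0.0771. Both measured egg cell genes, EC1;5 (-2.26 ± 0.46) and RKD2 (-3.71 ± 0.84), were lower when adjusted over the list alone and 0 over all genes. Of 322 ribosomal protein genes 0 passed over all genes or over the list alone. Their median log2 change was 0.30, or 0.13 with library totals, against medians of all genes of 0.01 and -0.18. Camera called that list (adjusted p = 0.000277, and adjusted p = 0.737 with an estimated correlation), but not without the 1-cell/2-cell Col-0 x Cvi-0 (0.663) or the 8-cell Col-0 x Cvi-0 library (0.351).

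The remaining lists were not called by camera. Adjusted p was 0.251 for 5 maternally expressed imprinted genes, for 21 seed coat genes and for 29 chromatin silencing genes, 0.491 for 13 maturation genes, 0.587 for 19 photosynthesis genes and 0.779 for 6 endosperm genes. Their members had 0 calls over all genes, and adjusted over the list alone the endosperm subtilase gene ALE1 was the 1 call (2 reads, then a ratio of 28.6 with a counting interval of 7.57 to 241, or 9.33 with 2.04 to 86.6 without the 8-cell Col-0 x Cvi-0 library). SHP1, a seed coat and ovule regulator, had 1056 ± 467 RPM and then 407 ± 72.4 RPM (log2 -1.16 ± 0.30, adjusted p = 0.159). The 2 measured pollen genes, VGD1 (-1.65 ± 1.53) and HAP2 (0.72 ± 1.32), had 0 calls.

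Between the 8-cell and 32-cell stages 0 genes passed in edgeR, with 2064 at an unadjusted 0.05, while DESeq2 called 282 higher and 365 lower. The genes nearest to the threshold, all short of it, included HP6, a cytokinin signalling component (0.285 ± 0.169 to 96.3 ± 81.7 RPM, log2 7.97 ± 0.75, adjusted p = 0.112), the organ initiation gene DRNL (log2 6.96 ± 0.65, adjusted p = 0.112), AT2G32690 (3.17 ± 0.36), SVB (4.08 ± 0.54) and AT1G71691 (2.28 ± 0.27), whose stage means were 14.7, 375 and 1862 RPM. On the lower side were AT2G07667 (-5.82 ± 0.50, adjusted p = 0.0618), the chaperone gene J11 (-3.68 ± 0.43), AT1G19396 (-3.25 ± 0.43), the heat shock factor gene HSFA7A (-2.15 ± 0.29) and RBCS2B (-5.28 ± 0.72). Leaving out 1 library gave 170 and 139 genes (1-cell/2-cell, Col-0 and Cvi-0 mother), 12 (32-cell Col-0 x Cvi-0) or 533 (32-cell Cvi-0 x Col-0), and 0 without either 8-cell library.

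Of 40 embryo patterning genes 0 passed over all genes in this comparison and 1, DRNL, when adjusted over the list alone. Camera called the list higher (adjusted p = 0.0182, and adjusted p = 0.896 with an estimated correlation), but not without the 32-cell (0.0673) or the 8-cell Cvi-0 x Col-0 library (0.0873). WOX2 and WOX9, homeobox genes of the early embryo axis, had log2 changes of -1.69 ± 0.44 and -1.23 ± 0.31 (adjusted p = 0.231 and 0.224). The 322 ribosomal protein genes had a median of 0.21 (0.16 with library totals; camera adjusted p = 0.0014, and adjusted p = 0.933 with an estimated correlation), with 0 calls of either kind, and adjusted p = 0.736 without the 8-cell Cvi-0 x Col-0 library. The median of all genes was 0.01, or -0.04 with library totals. RBCS2B among photosynthesis genes and TT6 among seed coat genes (1.92 ± 0.38) passed when adjusted over the list alone, the first lower and the second higher. No other list was called, with camera adjusted p of 0.819 for both imprinted lists and for endosperm genes, 0.854 for seed coat and photosynthesis genes, 0.522 for maturation and chromatin silencing genes and 0.202 for cell cycle genes. Pollen genes VGD1 (-3.34) and HAP2 (0.75) and egg cell genes EC1;5 (0.65) and RKD2 (0.25) had 0 calls.

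Between the reciprocal crosses, 1 of 17478 genes differed. AT2G07667, an uncharacterized gene on chromosome 2 (3364296 to 3366661, TAIR10.1), had 2915, 1140 and 28 reads with a Col-0 mother at successive stages and 2, 2 and 0 with a Cvi-0 mother (log2 -10.01 ± 0.44, adjusted p = 0.000447). It lies inside a stretch of nuclear DNA copied from the mitochondrial genome (3250465 to 3509757), so its reads are uncertain. Short of the threshold were, with a Cvi-0 mother, AT1G47950 (log2 4.51 ± 0.56, adjusted p = 0.436), RBCS2B (3.26 ± 0.53), the chlorophyll biosynthesis gene POR C (1.70 ± 0.28), AT1G77160 (3.71 ± 0.65) and FZR3 (1.44 ± 0.26), and with a Col-0 mother GSTU9 and AT5G52940 (both 0 reads with a Cvi-0 mother), AT1G65370 (-1.60 ± 0.25) and AT3G20340 (-5.08 ± 0.90). Each of 3 of these was read mostly in 1 library, GSTU9 (35.9 RPM) and AT5G52940 (28.8 RPM) in the 8-cell and AT3G20340 (44.5 RPM) in the 1-cell/2-cell Col-0 x Cvi-0 library. The test passed 992 genes at an unadjusted 0.05, and DESeq2 called 29 higher and 20 lower with a Cvi-0 mother. Without 1 library the count was 4 and 3 (1-cell/2-cell, Col-0 and Cvi-0 mother) or 31 and 34 (32-cell, same order). Library totals moved the median of all genes from 0.04 to 0.21.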

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

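Adding 0.5 of the allele reads to gene reads was chosen after seeing the data and changed no count by over 1.5 times. Over all stages, 9 genes differed by parent. The 9 were all maternal. No filter gave 54 genes (40 maternal and 14 paternal), DESeq2 22 (20 and 2) and the pooled binomial test 132 (82 and 50), while at least 50 reads gave 4 and the most-read variant alone 15, all maternal. Without each library the count was 4 to 12. For single stages it was 42 (23 maternal and 19 paternal), 32 (26 and 6) and 14 (13 and 1) with no filter (from 10, 7 and 3, earliest stage first). With at least 50 reads it was 0 at the 1-cell/2-cell and 1 at the 32-cell stage, and DESeq2 called 3 at the 8-cell stage. Without each library the ranges were 1 to 27, 0 to 28 and 4 to 15. The change between stages gave 18 genes with no filter and 0 to 21 without each library. The genotype count was within 1.5 times of 1430 under each alternative run, and all 130 alternative results for its named genes kept direction and call.

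From the 1-cell/2-cell to the 8-cell stage, 192 genes became 488 with no filter, 61 and 78 with the Col-0 or Cvi-0 allele alone, 814 in DESeq2 and 49 to 493 without each library. From the 8-cell to the 32-cell stage, 0 became 312, 10, 12, 647 and 0 to 533 under the same alternatives. The cross difference of 1 gene became 8 with no filter, 49 in DESeq2 and 1 to 34 without each library. Camera with an estimated correlation left 1 of 2 lists for the parent effect, 0 of 4 from the 1-cell/2-cell to the 8-cell stage and 0 of 2 from the 8-cell to the 32-cell stage. For the same lists, unadjusted fry p-values were 1.8e-07 (seed coat) and 0.041 (photosynthesis) for the parent effect. From the 1-cell/2-cell to the 8-cell stage, they were 0.0076 (paternally expressed imprinted genes), 0.0093 (patterning), 0.021 (cell cycle) and 0.22 (ribosomal proteins). From the 8-cell to the 32-cell stage, they were 0.017 (patterning) and 0.29 (ribosomal proteins). Lower counts with single alleles and stricter filters come with fewer reads or genes tested. For the other changes the cause was not tested.

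Without the 100 genes with the most reads the maternal share was 53.0%, 47.3%, 52.9%, 47.6%, 52.4% and 47.9% (stages in order, Col-0 mother first), with cross means of 50.1%, 50.3% and 50.2%. As a median over genes it was 52.4%, 47.8%, 52.6%, 48.5%, 52.2% and 48.2%, with means of 50.1%, 50.5% and 50.2%. Without genes read from 1 genotype it moved to 53.4%, 46.5%, 53.5% and 47.0% for the first 4 libraries and 47.2% for the last, and the 8-cell mean to 50.2%. Without the seed coat, endosperm and imprinted lists each share stayed within its interval. The binomial counts of 52, 38 and 12 became 131 and 74 at 2-fold (first and second stage), 27 at a threshold of 0.01 (first stage), and 14, 15 and 6 with at least 20 reads. For these moves, too, the cause was not tested.

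Among single genes, the log2 ratio reversed for AT5G05060 at the 8-cell stage (0.50 without the 8-cell Col-0 x Cvi-0 and -4.50 without the 8-cell Cvi-0 x Col-0 library) and AT1G21940 at the 32-cell stage (2.44 without the 32-cell Col-0 x Cvi-0 and -8.72 without the 32-cell Cvi-0 x Col-0 library), both short of the threshold. Named genes of the parent effect over all stages lost a call in 2 of 148 alternative results, those of the single stages in 43 of 109, 14 of 126 and 4 of 105 (earliest stage first), and those of the expression change from the 1-cell/2-cell to the 8-cell stage in 67 of 242. For the parent effects these totals include named genes short of the threshold, which had no call to lose, so the shares understate the losses. The 148 results also leave out AT5G47350, MBP2 and AT2G24693, which the naming rule did not take. Of all 9 genes called over all stages, 4 stayed called without the 32-cell Cvi-0 x Col-0 library. The number was 7 without the 8-cell Cvi-0 x Col-0 library and 8 in the pooled binomial test. At the 32-cell stage 3 of 5 maternal and 0 of 5 paternal named genes had passed. At the depth and spread of these libraries, the test for the 8-cell stage found 12% of simulated 2-fold effects. Mother and father alleles were compared within libraries, and stages with the cross direction as a block. No paired analysis was possible by replicate number, because each group had 1 library.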

Other observations

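The comparison of the 32-cell with the 1-cell/2-cell stage and the tests between crosses of gene lists were chosen only after the results were seen, as were the tests of seed coat RNA, of genotype or mapping and of egg carry-over for the maternal genes, those of the most-read genes and of genes read from 1 genotype for the Col-0 excess, and those of AT2G07667.

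Across the whole interval, from the 1-cell/2-cell to the 32-cell stage, 730 genes were higher and 630 lower of 17478 in edgeR. Of 40 embryo patterning genes 16 rose and 0 fell. They included the auxin response factor gene MP (log2 2.26 ± 0.29, 34.7 to 151 RPM), the leaf polarity gene PHB (1.88 ± 0.28), the boundary gene CUC1 (0.0777 to 35.5 RPM), SHR (0.0777 to 13.0 RPM) and PDF1 (5.06 ± 0.32). Of 39 cell cycle genes 7 rose, among them KNOLLE (3.16 ± 0.60), CYCD3;1 (3.33 ± 0.51) and the Aurora kinase genes AUR1 (2.00 ± 0.43) and AUR2 (1.66 ± 0.31). Without single libraries the patterning count was 9 (32-cell Col-0 x Cvi-0) to 16, and the cell cycle count 4 (1-cell/2-cell or 32-cell Col-0 x Cvi-0) to 10 (8-cell Cvi-0 x Col-0). The total of 1360 was 437 higher and 283 lower without the 1-cell/2-cell Col-0 x Cvi-0 and 334 and 225 without the 32-cell Col-0 x Cvi-0 library.

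Genes that fell over that interval included SUVH4, a histone H3 methyltransferase (-1.17 ± 0.27), the DNA methyltransferase gene DRM1 (-2.21 ± 0.47) and the Polycomb gene EMF2 (-1.47 ± 0.33), 3 of 29 chromatin silencing genes. That count was 0 without the 1-cell/2-cell Col-0 x Cvi-0 library or either 32-cell library, 1 without either 8-cell library and 2 without the 1-cell/2-cell Cvi-0 x Col-0 library. The egg cell gene RKD2 (-3.45 ± 0.83), the endosperm sucrose carrier SUC5 (-3.02 ± 0.55), the imprinted genes PEG2 (5.79 to 0.0307 RPM) and SAC2 (-2.17 ± 0.36), SHP1 (-1.78 ± 0.31), RBCS2B (-4.91 ± 0.72) and the storage genes SESA3 (-5.74 ± 1.35) and OLEO1 (6.18 to 0.0607 RPM) also fell, while ALE1 (0.0783 to 3.53 RPM) and L1L (3.88 ± 0.85) rose. Ribosomal protein genes gave 18 higher and 6 lower, with 76 higher without the 1-cell/2-cell Cvi-0 x Col-0 library, 1 without the 32-cell Col-0 x Cvi-0, 7 without the 1-cell/2-cell Col-0 x Cvi-0, 10 without the 8-cell Col-0 x Cvi-0 and 11 without the 8-cell Cvi-0 x Col-0 library. Pollen and maternally expressed imprinted genes had 0 calls. Between the crosses, the 322 ribosomal protein genes had a median log2 of -0.35 with a Cvi-0 mother, 30 of them above 0, or -0.18 with 60 above 0 under library totals (camera adjusted p = 2.78e-21, and adjusted p = 0.881 with an estimated correlation). The median of all genes between the crosses was 0.04, or 0.21 with library totals.

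RNA of the maternal seed coat may contribute to the maternal excess of the 9 genes over all stages, as the 7 measured seed coat genes had a median log2 ratio of 5.37, but the 4 not called had a median of 0.85, and GL2 and STK lay near 0. TT4, TT18 and BAN are among both the 7 and the 9, so the median of 5.37 is no independent test. The other genes of the 9 were not on the list, and the median says nothing about them. In these libraries of washed embryos 21 of the 26 listed genes passed the expression filter, with SHP1 (1056, 407 and 264 RPM by stage) and TT4 (22.1, 32.2 and 33.7 RPM) at the highest 8-cell means, which seed coat RNA and expression in the embryo would both give. For 8 genes the mother's allele held the majority in both pooled cross directions, at lowest 66.2% (57.6 to 74.1, MBP2). A genotype or mapping effect stays open for AT2G24693, with 36.9% (32.7 to 41.4). Its parent ratio came from a fit with a genotype term, so this share alone does not make genotype the cause of that ratio. These shares are no independent test, since the genes were called from the same reads and AT2G24693 was set apart after its value was seen. MBP2 and AT5G47350 also had no maternal majority in the 1-cell/2-cell Col-0 x Cvi-0 library. Egg carry-over cannot be told apart from seed coat RNA by the change of the 9 genes up to the 32-cell stage. That change had a median of 0.73 with quartiles of -1.07 and 1.68, and 6 of 9 were above 0. Splits of the 6 libraries were too few for a share under 0.05 (1 of 10 as large, 9 genes against 0 in the highest other), and maternal expression within the embryo remains untested.

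The excess of Col-0 allele reads, 52.9% to 54.0% per library, was not removed with the 100 most-read genes left out (lowest library 52.1%) or with genes read from 1 genotype left out (lowest 52.8%). Loss of Cvi-0 reads to further variants near the known ones could contribute. Genes with at least 5 variants had a median log2 of Col-0 over Cvi-0 of 0.18 (3778 genes) against -0.01 for genes with 1 variant (766 genes), a difference of 0.19 (bootstrap interval 0.13 to 0.25). The number of variants also goes with gene length and expression, so the test is not specific, and a biological difference between the accessions stays open. Chance is argued against for the genotype effect as a whole, since 1 of 31 assignments of the allele labels, the real one, gave 1430 genes and the highest other gave 0. In the other assignments the real allele differences went into the spread, so the test gives no share of false calls among the 1430.

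AT2G07667, the gene that differed between the crosses, was read almost wholly with a Col-0 mother. A nuclear Col-0 allele active from either parent is argued against, since libraries with a Col-0 father held 0.0979% of its 4087 reads (0.0267 to 0.250). A first form of the mitochondrial explanation, a difference between the mothers over the whole copy on chromosome 2, is also argued against by a median of 0.0895 over 83 other genes, and the next form was written after that value was seen. Mitochondrial transcripts read at the copy remain a candidate explanation, as the 83 genes had a median log2 change of -2.53 (-2.70 to -2.30) up to the 32-cell stage against 0.00 over all genes, though a joint fall also fits other causes and a mitochondrial sequence difference between the accessions was not tested. Splits of the libraries were again too few (1 of 10 as large, 1 gene against 0).

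A negative result concerned RNA inherited from the egg cell and lost by the 8-cell stage. Genes at least 4-fold lower at the 8-cell stage would then have a maternal excess at the 1-cell/2-cell stage. The median log2 ratio of mother over father was -0.05 for 124 such genes and -0.01 for 5842 genes within 2-fold, a difference of -0.042 (bootstrap interval -0.24 to 0.06), short of the excess of 0.5 set beforehand.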
